A study of Zea mays with 36 samples.

How the data were processed

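RNA of laser-captured shoot apical meristems (SAM) with the P0 and P1 leaf primordia was compared on cDNA slides with RNA of whole above-ground seedlings, all from maize B73 plants of 14 days. Per the labels, each of 6 biological replicates was a pair of RNA pools, from 6 to 10 meristems and from 6 seedlings of the same batch of plants. Meristem and seedling RNA were extracted by different procedures, so extraction and tissue cannot be told apart. About 10 ng of each was amplified by T7 polymerase, and 2 µg of amplified RNA was labelled. Dyes were swapped between odd and even replicates to remove dye effects in the statistics. Each replicate was hybridised to 1 slide of each of 2 sets carrying different clones, and 3 of 7 scans per slide were deposited, at low, medium and high laser power and gain.

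The deposited values were read as a natural log of the ratio of the channels, and were converted to log2 here. No source used here states the log base: it was taken from the values, in which spots with a channel at a floor of 1 lay 2 natural logs of a whole number apart in 174 pairs, against 13 pairs for log2 and 39 for log10. The deposited values were already turned so that all slides ran the same way, since slides of opposite dye orientation correlated positively. The normalization method, background handling and the tissue in the numerator are not given in the sources used here. Column medians lay within 0.08 log2 of 0 before any step here. The direction is called likely only, from the photosynthesis list, by a rule written before the data were examined.

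Of 19200 spots on the first slide set, 898 held no value and 18302 were used. Of 14080 on the second, 2001 held no value, and 53 spots identical in all scans were counted as 1 probe, which left 12027. Probe names came from the platform's gene annotation, and symbols from a gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. Probes matching several genes (23 on the first set) were not used for gene values, and most probes had no name. Gene values are the mean of a gene's probes on a slide. For 15 genes the name printed was picked among the gene's own synonyms after the data were examined.

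Each scan was centred on its median and the 3 scans of a slide were averaged, giving 6 values per probe and set. A probe needed values in 4 replicates and 2 of each dye orientation, which all met. limma 3.58.1 in R 4.3.3 fitted an intercept and a dye term (lmFit, eBayes), with Benjamini-Hochberg adjustment over the probes or genes of a set and a threshold of 0.05. SDs are over the 6 slides and include variation with the dye. The number of slides limits the precision; the median standard error of a probe was 0.159 on the first set and 0.119 on the second. Lists of genes were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a set, and again with an estimated correlation. Camera compares a list with the other named genes of the set, and a list is said to pass or not by camera. limma's fry, which tests the members of a list against 0, was also run and adjusted over the lists. It was not in the plan fixed beforehand. The scan comparison used an exact permutation test. Data were handled with the R package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and drawn with matplotlib 3.10.9.

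Lists, tests, alternatives and the rule for named genes were fixed before the data were examined, except as stated. The rule named, in each slide set, the 8 highest and 8 lowest genes past the threshold with the same sign on all slides. It also named, in each list, the 2 members with the smallest adjusted p in each direction among those past the threshold, and a fixed set of meristem and C4 genes wherever measured. It gave 69 genes on the first set and 62 on the second. Fixed names that were not found, such as gn1, td1, pep1 and cab1, gave no value. Of 23 lists, 15 were tested on the first set and 16 on the second, each with at least 3 measured genes. Too small in both were respiration, RNA processing and RNA silencing, with 2, 2 and 1 genes on the first set, and plastid ribosomal proteins, proteolysis and transposons had none. Lists were matched by name patterns, and members that matched by name only were identified after the values were seen.

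The alternatives were no centring, slides scaled to the same spread, each scan alone, no dye term, a robust eBayes, a value in every replicate, a 2-fold limit, each replicate left out, each dye orientation alone and an estimated correlation. Spots with both channels at the floor of a scan left out, and lists without members matched by name only, were added after seeing the data. The scripts were tested on simulated data with 200 changed probes per set. In the real sets 11437 and 7769 probes passed, so the Benjamini-Hochberg adjustment was stricter in the simulation. The shares recovered there therefore do not give the recovery in the real data. At log2 changes of 0.5, 1 and 2 the first set's design recovered 3%, 41.8% and 84.8% of them, with 4.4% false among the calls, and the second set's recovered 20.9%, 70.1% and 81.8%, with 7.3% false. Simulated on the genes of the chromatin list, a shift of 1 was missed on the first set (adjusted p = 0.526 over 582 genes) and called on the second (0.0243 over 455), and a shift of 2 was called on both (0.00446 and 5.96e-05). An earlier form of that simulation, with normally distributed gene effects, missed the shift of 2 on both sets. It was replaced by the measured effects shuffled among genes. The form used was a single draw per set, and the shuffle gave the list effects from all named genes. It therefore gives no detection rate for the measured lists.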

Results

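Transcript levels in the shoot apical meristem (SAM) of maize, the dome of stem cells from which leaves and stem arise, were compared with those of the whole above-ground seedling. Plants of the inbred line B73 were 14 days old. Each of 6 biological replicates paired RNA from 6 to 10 meristems, cut out by laser capture together with the youngest leaf primordia, with RNA from 6 seedlings. The pairs were hybridised to 2 sets of cDNA slides carrying different clones, so that 12 slides and 36 scans were available, 3 scans at rising laser power per slide. SAM RNA carried Cy3 on 3 slides of each set and Cy5 on the other 3. For 1 scan, the high scan of replicate 4 on the first set, the source label names seedling tissue for both dyes; its sample name and the other scans of that slide place SAM in Cy5, which was followed. The first slide set gave values for 18302 probes and the second for 12027, of which 1787 and 753 could be named, standing for 582 and 455 genes. The number of slides limits the precision, and no signal intensities were used here. The comparison asks which transcripts are preferentially found in the meristem; the seedling RNA itself includes meristem.

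No source used here states which tissue is the numerator of the deposited ratio. The photosynthesis genes lay far on the negative side in both slide sets, and this list as a whole passed its test (camera adjusted p = 0.00705 and 0.000501). With an estimated correlation between genes, which leaves the ratios as they are, the list did not pass (adjusted p = 0.485 and 0.465). Its medians were −5.71 and −4.53, and 10 of 13 and 11 of 11 members passed on the negative side, each as the mean of its probes. A positive ratio is therefore called the SAM side and a negative one the seedling side, as the likely direction, since it is inferred and not stated. All ratios are relative to the median probe of a slide. The camera test compares a list with the other named genes and not with 0. Of the named genes that passed, more lay on the seedling side (263 against 158 and 208 against 127). A list can therefore lie toward the SAM side by camera with a median or mean below 0.

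On the first slide set the genes farthest to the SAM side included TE1 (terminal ear1, a MEI2-like RNA-binding protein that restricts leaf initiation), at a log2 ratio of 6.77 ± 0.91 (SD, n = 6), and lbl1 (leafbladeless1, a protein of the small RNA pathway that sets leaf polarity), at 2.60 ± 0.22. The genes farthest to the seedling side were led by the catalase CAT3 at −10.64 ± 1.16 and included subunits of photosystem I, psad1 at −10.01 ± 2.72, psah1 at −9.51 ± 1.37 and psan1 at −8.70 ± 1.34. In limma with Benjamini-Hochberg adjustment, 11437 of 18302 probes passed an adjusted p of 0.05, 5759 on the SAM side and 5678 on the seedling side. Of the probes that passed, 78.6% had the same sign on all 6 slides; among all probes 50.3% did, where chance alone gives 3.125%. With a change of at least 2-fold also asked for, 3060 probes remained on the SAM side and 3559 on the seedling side. Among the named genes 421 of 582 passed, 158 on the SAM side and 263 on the seedling side.

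The other genes at the SAM end of the first slide set were ae1 (starch branching enzyme IIb) at 4.78 ± 0.93, zr1 at 4.64 ± 1.34, tacs1 at 4.37 ± 0.85, LOC542345 at 3.17 ± 0.64, nip3a (an aquaporin of the NIP family) at 2.66 ± 1.05 and PEAMT (phosphoethanolamine methyltransferase) at 2.66 ± 0.94, all with 6 of 6 slides on that side and adjusted p between 8.82e-06 and 0.000483. The dye term was positive where the ratio was higher with SAM in Cy3. It gives the distance of either orientation from the mean of both, not the difference between them. On the log2 scale it was −1.13 for zr1 and −0.90 for nip3a (limma adjusted p = 0.0396 for each). PEAMT lay on the other side of 0 on the second slide set, at −1.82. The seedling end was completed by the pathogenesis-related gene pr5 at −10.10 ± 3.56, the beta-amylase BMY1 at −9.76 ± 2.69, the aquaporin pip1e at −8.62 ± 1.92 and opr5 (an oxo-phytodienoate reductase) at −8.41 ± 2.04. With the same RNA pairs on the second slide set, pr5 lay at −1.50 ± 0.41, BMY1 at −4.95 ± 0.40 and opr5 at −4.87 ± 0.96. How close the weaker channel of these genes lay to the floor of the scanner values cannot be read from a ratio, so folds of this size are imprecise. At the ends of the first set lbl1 had 4 probes and CAT3 2. Each other gene there had 1 probe, so its value is that of a single clone.

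**Figure D1:**
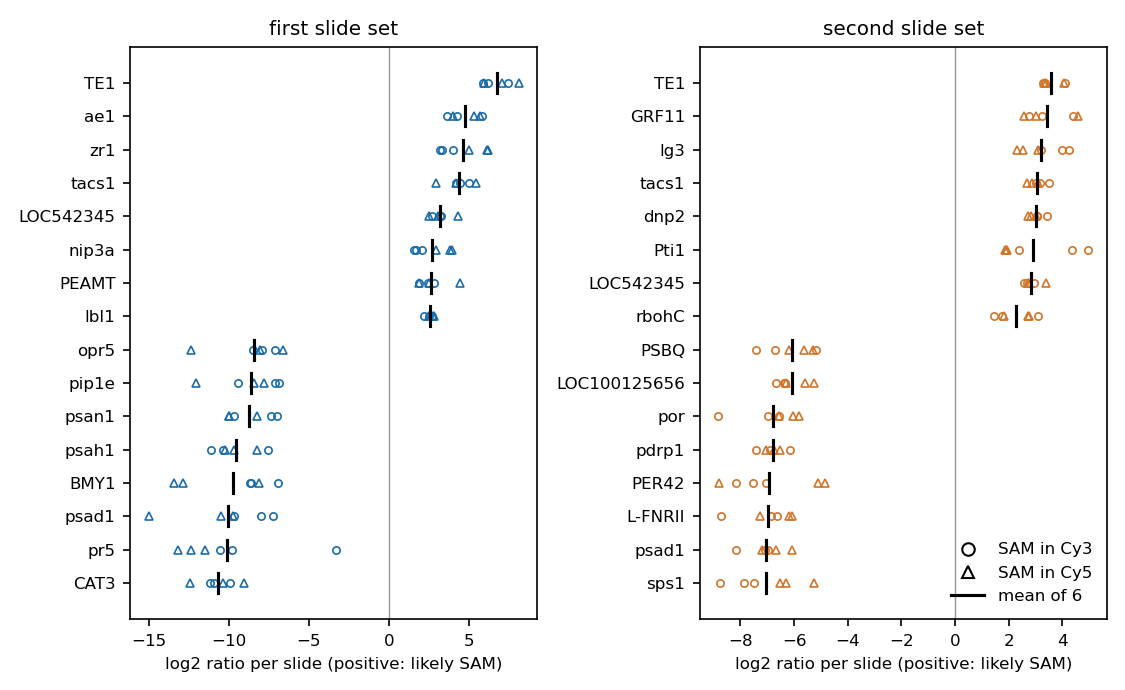
Log2 ratio of each slide for the 8 named genes with the highest and the 8 with the lowest mean in each slide set, among genes past the threshold with the same sign on all 6 slides. Circles are slides with SAM in Cy3, triangles slides with SAM in Cy5, and bars the mean of 6; TE1 leads the SAM side in both sets, at 6.77 and 3.58.

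Of 13 photosynthesis genes on the first slide set, 10 passed on the seedling side, 1 passed on the SAM side and 2 did not pass, with a list median of −5.71. The small subunit of Rubisco (ssu1) lay at −5.71 ± 0.60 and the malate dehydrogenase mdh6 at −5.73 ± 0.43, and the malic enzyme ME1, which releases CO2 in bundle sheath cells, at −4.18 ± 0.43. The exception was the chlorophyll-binding gene Cab-m7 at 1.09 ± 0.92, which lay at −4.28 on the second slide set. On the second slide set all 11 measured members passed on the seedling side, with a median of −4.53. They included ssu1 at −5.64 ± 0.40, the light-harvesting gene lhcb5 at −6.02 ± 0.46 and Ppdk1, the pyruvate phosphate dikinase of C4 photosynthesis, at −4.53 ± 0.59. The value of lhcb6, another of the 11, was a mean of 4 probes between −6.89 and 1.71, of which 2 passed on each side. Adjusted over the list alone, the counts were the same (10 and 11 on the seedling side). The list passed the camera test in both sets (adjusted p = 0.00705 and 0.000501), and in neither with an estimated correlation (adjusted p = 0.485 and 0.465). Of the chlorophyll and plastid synthesis list, 4 genes were measured on the second set and 3 passed on the seedling side, among them por at −6.80 ± 1.08 and oy1, a subunit of magnesium chelatase, at −4.75 ± 0.98. The list did not pass as a whole (adjusted p = 0.151). The third was porin1, matched by name only, at −1.31. On the first set 2 members were measured and not tested as a list, of which porin1 passed at −1.12 ± 0.33.

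Of 20 chromatin genes on the first slide set, 17 passed on the SAM side, none on the seedling side and 3 did not pass, with a median of 1.13 and a camera adjusted p of 2.08e-07. The list did not pass with an estimated correlation (adjusted p = 0.0889). Gene values are means of probes. Of the probes of hda106, nfd101 and hdt102, 1, 8 and 5 passed on the SAM side and 1 of each on the seedling side. The histone acetyltransferase gene hac106 lay at 2.06 ± 0.28 and the Polycomb gene fie2 at 1.74 ± 0.64, with a dye term of 0.57 (adjusted p = 0.0396). On the second slide set 15 of 18 passed on the SAM side, 1 on the seedling side and 2 did not pass, with a median of 1.09 and an adjusted p of 5.77e-05. This call too was lost with an estimated correlation (adjusted p = 0.225). Those that passed included nfc102 at 1.80 ± 0.14 and nfc101 at 1.78 ± 0.18. The member that passed on the seedling side was hac108, at −3.79 ± 0.21. Adjusted over the list alone, 17 and 15 genes passed on the SAM side. Of 3 histone genes on the first set, 1 passed, his2b5 at 1.25 ± 0.18 (1.20 ± 0.18 on the second set, where it was the sole member), and the list did not pass (adjusted p = 0.38).

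Of 16 regulators of meristem and leaf initiation on the first slide set, 11 passed on the SAM side, 1 passed on the seedling side and 4 did not pass, with a median of 0.89 and a camera adjusted p of 0.00317. The list overlaps the epidermis list below, sharing ocl1, ocl2 and ocl4 on the first set and ocl1, ocl3 and ocl4 on the second. The list did not pass with an estimated correlation (adjusted p = 0.485) or on the slides with SAM in Cy5 alone (adjusted p = 0.0516). The members with the smallest adjusted p were lbl1, above, and rs2 (rough sheath2, which keeps knotted1-like genes off in leaf primordia) at 1.67 ± 0.23. The branching gene BA1 lay on the seedling side at −1.13 ± 0.35. On the second slide set 7 of 12 passed, all on the SAM side, and 5 did not pass, with a median of 0.35 and an adjusted p of 0.00783. With an estimated correlation this list did not pass (adjusted p = 0.225). Its members included fea2 (fasciated ear2, a receptor-like protein that limits meristem size) at 1.88 ± 0.34 and rs2 at 1.52 ± 0.34. Adjusted over the list alone 11 and 5 members passed on the SAM side. Of other members, chosen after their values were seen, the leaf polarity gene rld1 lay at 1.49 ± 0.24 on the first set and 1.40 ± 0.31 on the second, and yabby15 at 1.61 ± 0.64 on the second. The WUSCHEL-type homeobox gene ns2 (narrow sheath2) lay at 0.85 ± 0.92 (adjusted p = 0.0372) and 0.05 ± 0.16 (adjusted p = 0.61), and wox13B at −0.06 ± 0.54 (adjusted p = 0.714). The call of ns2 on the first set ended in the low scan alone, without the dye term, on the slides with SAM in Cy3 alone (0.39), and without replicate 1 (0.61), 2 (0.92), 5 (0.96) or 6 (0.60).

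Of the knotted1-like homeobox genes, kn1 marks cells that stay undetermined. It lay at 0.30 ± 0.25 on the first slide set (adjusted p = 0.0322) and at 1.95 ± 0.37 on the second (adjusted p = 8.46e-06). The first of these calls ended without the dye term, on the slides with SAM in Cy3 alone (0.13), and without replicate 1, 2, 3, 4 or 6, at ratios between 0.25 and 0.30. The gene lg3 (liguleless3) lay at 0.70 ± 0.40 and 3.22 ± 0.77, and knox7 at −0.79 ± 0.37 on the first set. As a list, 2 of 3 members passed on the SAM side and 1 on the seedling side of the first set (camera adjusted p = 0.64), and 3 of 4 on the SAM side of the second (adjusted p = 0.0818).

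Among DNA replication and cell cycle genes, 9 of 12 passed on the SAM side of the first slide set and 1 on the seedling side, with a median of 1.06 and a camera adjusted p of 0.00317. With an estimated correlation this call was lost (adjusted p = 0.276). The replication clamp gene pcna2 lay at 1.32 ± 0.12 and the cyclin cyc1 at 2.01 ± 0.55. On the second slide set 7 of 14 passed on the SAM side and 2 on the seedling side, and the list did not pass (median 0.55, adjusted p = 0.125). There pcna2 lay at 1.22 ± 0.35 and the retinoblastoma-related gene rbr3 at 1.99 ± 0.33. Several members answered to the name pattern only: a cyclotide gene at −8.16 ± 2.51 and −5.23 ± 0.47, the kinesin kin4 at 1.47 ± 0.33 on the first set, and the kinesins kin15 at −1.18 ± 0.35 and krp6 at 0.40 ± 0.13 on the second. Leaving out such members, a choice made after the values were seen, gave 8 of 9 on the SAM side of the first set (adjusted p = 0.00151) and 6 of 10 on that of the second (adjusted p = 0.0184), with none on the seedling side of either. With an estimated correlation neither of these passed (adjusted p = 0.398 and 0.465). Of the replication helicase, chosen after the values were seen, MCM6 lay at 2.03 ± 0.70 and 1.35 ± 0.62, and MCM7 at 1.03 ± 0.49 and 1.81 ± 0.88.

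Of 24 stress and defence genes on the first slide set, 17 passed on the seedling side, 3 on the SAM side and 4 did not pass, with a median of −1.69 and a camera adjusted p of 0.0466. This call was lost with an estimated correlation (adjusted p = 0.485). Besides CAT3 and pr5, the latter at −1.50 on the second set, they included the glutathione transferase gst1 at −2.22 ± 0.15 and prp2 at −3.03 ± 0.59, while GST38 at 1.79 ± 0.40 and gst41 at 1.12 ± 0.18 lay on the SAM side. On the second slide set 8 of 15 passed on the seedling side and 3 on the SAM side, and the list did not pass (median −0.96, adjusted p = 0.405). There gst12 lay at −5.07 ± 0.46 and prp2 at −2.86 ± 0.43, against gst31 at 0.90 ± 0.27 and Sod4A at 0.36 ± 0.39. The call of Sod4A ended in the high scan alone, without the dye term and on the slides with SAM in Cy3 alone, at 0.06. The list call on the first set was also lost in the medium scan alone, the high scan alone, without the dye term, in each dye orientation alone and without replicate 5 (adjusted p = 0.062).

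On the second slide set the SAM end was again led by TE1, at 3.58 ± 0.38, followed by GRF11 at 3.43 ± 0.85, lg3, tacs1 at 3.06 ± 0.28, dnp2 at 3.02 ± 0.25, the kinase gene Pti1 at 2.90 ± 1.39, LOC542345 at 2.85 ± 0.29 and rbohC, an NADPH oxidase, at 2.27 ± 0.68. The seedling end held sucrose phosphate synthase (sps1) at −7.04 ± 1.27, psad1 at −7.03 ± 0.69, the leaf ferredoxin reductase L-FNRII at −6.96 ± 0.96, the peroxidase PER42 at −6.93 ± 1.62, pdrp1, which regulates pyruvate phosphate dikinase, at −6.80 ± 0.44, por, LOC100125656 at −6.09 ± 0.55 and PSBQ, of the oxygen-evolving complex, at −6.07 ± 0.87. On the first set PER42 lay at −5.12 and LOC100125656 at −8.09. At the ends of the second set tacs1, PSBQ, L-FNRII and psad1 had 2 probes each and the other genes 1. Of 12027 probes 7769 passed, 4020 on the SAM side and 3749 on the seedling side, and 84.1% of them had the same sign on all 6 slides. With at least a 2-fold change 1737 and 2138 remained. Among the named genes 335 of 455 passed, 127 on the SAM side and 208 on the seedling side.

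The walls of the shoot were represented by 11 genes on the first slide set, of which 8 passed on the seedling side and 3 on the SAM side (median −1.72, camera adjusted p = 0.38). The lignin enzymes CAD2 (cinnamyl alcohol dehydrogenase) at −3.59 ± 0.52 and pal3 (phenylalanine ammonia lyase) at −1.76 ± 0.17 lay on the seedling side, while HRGP, a hydroxyproline-rich wall protein, at 2.11 ± 0.26 and the cellulose synthase cesa3 at 0.80 ± 0.36 lay on the SAM side. On the second set all 5 members passed on the seedling side (camera adjusted p = 0.125). They included the cellulose synthases cesa7 at −3.64 ± 0.30 and cesa2 at −2.99 ± 0.31. By fry, against 0, the wall list had adjusted p = 1.45e-05 and 8.97e-05 in the sets. The sucrose synthase sus1 lay at −2.60 ± 0.17 and −2.27 ± 0.33 in the 2 sets, and a second sucrose synthase, sh1, at 0.53 ± 0.14 and 0.68 ± 0.31. The vascular and sugar transport list had 2 members on the first set and was not tested there, and did not pass with its 3 members on the second (adjusted p = 0.591). Of nitrogen assimilation genes 2 of 3 and 4 of 6 passed on the seedling side (adjusted p = 0.287 and 0.428), with the glutamine synthetases gln1 at −2.51 ± 0.30 and −4.28 ± 0.25 and GLN6 at −2.90 ± 0.75 on the first set. On the second, the glutamate dehydrogenase gdh1 lay at −1.35 ± 0.29 and gln4 at 0.38 ± 0.20.

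Ribosomal protein and translation factor lists did not pass camera in either slide set. By fry, against 0, ribosomal proteins had adjusted p = 0.588 and 0.151, and translation factors 0.0089 and 0.000439. The list values that follow are of camera. Of 16 cytosolic ribosomal protein genes in each set, 4 and 7 passed on the SAM side and 4 and 3 on the seedling side (medians 0.16 and 0.20, adjusted p = 0.267 and 0.125). The mean on the first set was −0.05, on the other side of 0 from its median and its camera test. On the seedling side lay rpp2b at −2.99 ± 0.29 and −2.50 ± 0.37, and rpl30 at −0.54 ± 0.40 and −0.49 ± 0.19. On the SAM side lay arpp2a at 0.61 ± 0.07 and rps21b at 0.67 ± 0.37 on the first set. The second set had rpl2 at 1.71 ± 0.33 and rpl17 at 0.58 ± 0.17 on the second. Translation factors passed in both directions, 3 and 2 on the SAM side against 7 and 3 on the seedling side (adjusted p = 0.982 and 0.884). The initiation factor tif1 lay at −2.26 ± 0.49 and −2.10 ± 0.22, EF1-A at −0.65 ± 0.26 and −1.27 ± 0.39, eif3 at 0.38 ± 0.23 and 0.86 ± 0.25, and eif7 at 0.83 ± 0.30 on the first set. On the first set eif5a passed on the seedling side, at −0.66 ± 0.32 from 7 probes, and on the second on the SAM side, at 0.44 ± 0.33 from 1 probe. The second of these calls ended with SAM in Cy5 alone, at 0.15. The call of eif3 on the first set ended without replicate 2, at 0.35, and with SAM in Cy5 alone, at 0.25.

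Hormone, cytoskeleton, epidermis and chaperone lists did not pass camera in either slide set. By fry, against 0, the cytoskeleton list had adjusted p = 0.0118 and 0.000229 in the sets. The hormone list had 0.296 and 8.97e-05, and without members matched by name only 0.769 and 0.858. Chaperones had 0.168 and 0.00153, and epidermis 0.0812 and 0.961. The list values that follow are of camera. Of 10 and 11 hormone genes, 2 passed on the SAM side in each set and 6 on the seedling side (adjusted p = 0.982 and 0.753). The response regulators RR9 at 1.52 ± 0.25 and RR4 at 1.24 ± 0.20 on the first set and the histidine kinases HK1 at 1.33 ± 0.41 and hk3 at 0.35 ± 0.30 on the second lay on the SAM side. On the other set of each, RR4 lay at 0.33 ± 0.51 (adjusted p = 0.0561) and hk3 at 1.51 ± 2.80 (adjusted p = 0.224), and the second-set call of hk3 ended in the high scan alone and with SAM in Cy5 alone, at 0.11. On the seedling side lay arf1 at −1.03 ± 0.28 on the first set and, answering to the name pattern only, the actin-binding ADF3 at −0.93 ± 0.32 and −1.10 ± 0.26 and adf2 at −2.67 ± 0.55 on the second. Without members matched by name only, a choice made after the values were seen, 2 of 9 and 2 of 8 passed on the SAM side and 5 and 3 on the seedling side (adjusted p = 0.988 and 0.687), with the camera test turned to the SAM side while the medians stayed negative (−0.34 and −0.19). Of 19 cytoskeleton genes in each set, 5 and 2 passed on the SAM side and 9 and 13 on the seedling side (adjusted p = 0.988 and 0.405). They included the tubulins tub3 at 1.87 ± 0.49, tub4 at −3.0 ± 0.49 and tub6 at −0.82 ± 0.13 on the first set and the kinesin KIN8 at 1.68 ± 0.40 on the second. The epidermal homeobox gene ocl4 lay at 1.22 ± 0.50 and 2.24 ± 0.80 and ocl2 at 0.94 ± 1.21 on the first set, against the wax gene gl8 at −2.38 ± 0.43 on the first set and the lipid transfer gene plt2 at −0.73 ± 0.19 on the second (list adjusted p = 0.708 and 0.617). The epidermis list had a median of 0.44 and a mean of −0.07 on the first set, and a median of 0.00 below its mean of 0.38 on the second, with the camera test toward the SAM side in both. The slides with SAM in Cy5 alone put ocl2, which lay on the SAM side on 5 of 6 slides, at −0.05 (adjusted p = 0.775), and its call also ended without the dye term (adjusted p = 0.0856). Of 5 chaperone genes in each set, 2 passed on the SAM side in each and 1 on the seedling side of the first (adjusted p = 0.718 and 0.151). On the first set hsp70-5 lay at 0.37 ± 0.16, bip1 at 0.37 ± 0.32 and hsp22 at −0.82 ± 0.15. On the second mtcpn60II lay at 0.96 ± 0.24 and hsp101 at 0.81 ± 0.70. The call of bip1 ended in the low scan alone, without the dye term, in each dye orientation alone and without replicate 1, 3, 4, 5 or 6, at ratios between 0.28 and 0.42 without them. The chaperone list of the first set had a median of 0.01 and a mean of −0.05. In the lists of this and the preceding paragraphs for which it is not given, the counts adjusted over the list alone were the same as those over all genes. The mitochondrial ATP synthase gene ATP2 lay at −1.25 ± 0.38 and −1.10 ± 0.27, in a respiration list too small to test.

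**Figure D2:**
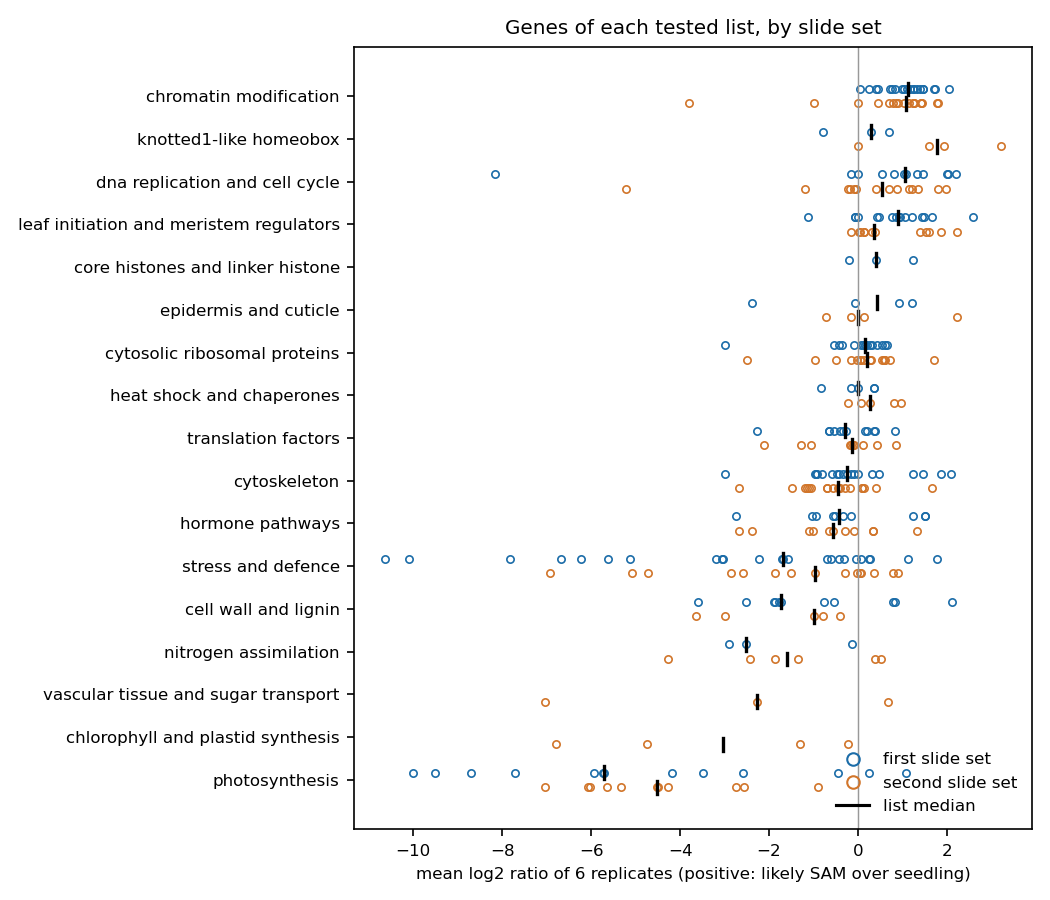
Mean log2 ratio over 6 replicates of each measured gene, by list, for the first (blue) and second (orange) slide set, with the list median as a black bar; only lists with at least 3 measured genes are drawn. The chromatin medians are 1.13 and 1.09, and the photosynthesis medians −5.71 and −4.53.

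Both slide sets received the same RNA pairs, so their comparison measures hybridisation and probes, not new plants. Of 297 genes on both sets, 176 passed in both, and 166 of these (94.3%) lay on the same side. Across genes, which are not independent replicates, the mean ratios correlated with r = 0.766 and rho = 0.778. The largest contrasts among the 10 genes on opposite sides, chosen after their values were seen, were gst31 (−7.82 and 0.90), the fatty acid desaturase fad7 (−4.92 and 0.67; dye term on the first set 1.93, limma adjusted p = 0.00451), Cab-m7 and PEAMT. In PSBQ a ratio of 0.26 ± 0.36 on the first set, which did not pass (adjusted p = 0.109), stood against −6.07 on the second.

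**Figure D3:**
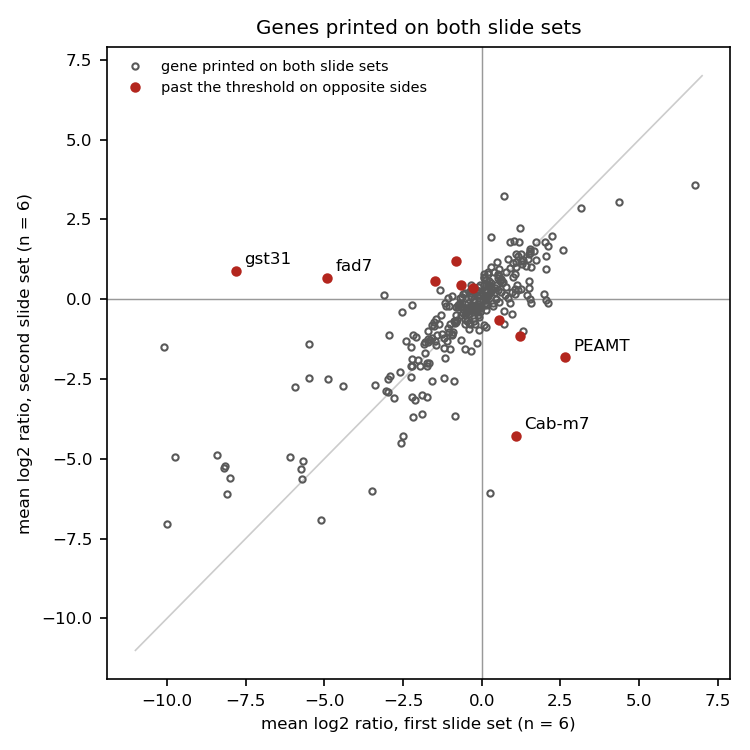
Mean log2 ratio of the 297 genes printed on both slide sets, first set on the horizontal axis and second on the vertical, each over 6 replicates, with the line of equal values. Filled points are the 10 genes past the threshold on opposite sides.

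Probes of the same gene also differed within a slide set. Of 201 genes with at least 2 probes past the threshold on the first set, 45 had probes past it in opposite directions, and on the second set 9 of 124 did. EF1-A, with 24 probes on the first set, had 2 that passed on the SAM side and 5 on the seedling side.

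The ratio differed between the dye orientations in 2322 probes on the first slide set (12.7%) and 1012 on the second (8.4%), by the limma test of the dye term. In the low scan alone 11 probes passed on the first set and 414 on the second, and in the medium scan of the first set 1540. Slides of the same dye orientation correlated across probes with a median r of 0.884 and 0.868, and slides of opposite orientation with 0.770 and 0.664. Of the genes named by the rule fixed beforehand, zr1, nip3a and fie2 had a dye term past the threshold, all on the first set. Calls that ended in a single dye orientation, besides those given above, were Cab-m7, lg3, hsp70-5, knox7, cesa3 and rps21b on the first set, hsp101, krp6, gln4 and sh1 on the second, and rpl30 on both. Dye orientation coincides with odd and even replicate numbers, so a difference between those RNA pairs would enter the same term.

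The spread of the log2 ratios was lower in the high than in the low scan on most slides, without passing adjustment. The mean difference in median absolute deviation, high minus low, was −0.0786 on the first set, lower on 6 of 6 slides (exact paired permutation test, two-sided, p = 0.0312, the smallest that 6 slides allow; Benjamini-Hochberg adjusted over 6 such tests, p = 0.0624). On the second set it was −0.075, lower on 5 of 6 slides (exact p = 0.0625, adjusted p = 0.0938).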

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

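The test of a difference between odd and even RNA pairs was chosen only after the result was seen, and the other tests of explanations here were written beforehand. Of 166 values tested for a slide far from the other 5, 12 stood out (7.2%), where chance gives about 5%.

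PEAMT on the first set stood at 4.4186 in replicate 6, with the others between 1.8722 and 2.8044. GST38 on the first set stood at 2.5467 in replicate 1, above the others at 1.4269 to 1.8305. RR9 on the first set stood at 1.0334 in replicate 1, below the others at 1.4987 to 1.7139. The translation factor eif3 stood at −0.074 in replicate 6 of the first set, with the others between 0.3713 and 0.561. ATP2 on the first set stood at −0.501 in replicate 4, with the others between −1.5022 and −1.2292. The wax gene gl8 stood at −1.5508 in replicate 5 of the first set, with the others between −2.6798 and −2.3123. The gene opr5 stood at −12.3425 in replicate 2 of the first set, with the others between −8.454 and −6.5865. The defence gene pr5 stood at −3.2751 in replicate 5 of the first set, with the others between −13.1554 and −9.769. On the second set nfc102 stood at 2.062 in replicate 1, above the others at 1.6701 to 1.8061. The mean of the chlorophyll and plastid synthesis list was −4.1919 in replicate 3 of the second set, with the others between −3.1757 and −2.9725. The mean of the cytoskeleton list was −0.3611 in replicate 4 of the second set, with the others between −0.5871 and −0.5168. The mean of the DNA replication and cell cycle list was 0.723 in replicate 3 of the second set, with the others between −0.024 and 0.1718.

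The ratio differed between the dye orientations in zr1 (dye term −1.1287), nip3a (−0.8966) and fie2 (0.5722) on the first set, each with a limma adjusted p of 0.0396.

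These genes belong to a wider group of 2322 and 1012 probes whose ratio moved with the dye orientation. The share with both channels at the scanner floor in at least 1 scan was 0.84 and 0.54 times that of other probes. Such a spot takes 1 value shared within the scan, not a dye difference of its own probe. In low scans of the first set that value moved with the orientation, before centring. It was −0.1045, −0.1 and −0.1223 natural log with SAM in Cy3, against 0.0395, −0.0001 and −0.0342 with SAM in Cy5. In the medium and high scans of that set the orientations overlapped. These shares therefore cannot decide whether dim spots contribute. A floor in a single channel cannot be read from a ratio, so dim spots stay open. A dye bias of the transcript, and a difference between the odd and even RNA pairs, would both recur on the second set, but across 297 genes the dye terms of the sets correlated with r = −0.038 (permutation p = 0.504). Position on the slide may contribute: dye terms of probes adjacent in number, a stand-in for position, correlated with r = 0.47 and 0.414, against 0.07 and 0.148 for tissue terms. No biological explanation beyond the RNA pairs was tested, and of the 10 splits of the slides by dye none but the real one (2322 and 1012 probes) gave any probe (highest other 0), which are too few splits for a share under 0.05.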

How the results depend on the processing

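Spots at the floor left out, and lists without members matched by name only, were chosen only after the result was seen. The probe counts stayed within 1.5 times the reported ones in all alternatives but the 2-fold limit, which by construction left 6619 (3060 on the SAM side, 3559 on the seedling side) and 3875 (1737 and 2138); without single replicates they were 10194 to 10999 and 7083 to 7454. With an estimated correlation 0 lists passed in either set. On the first, adjusted p was 0.0889 for chromatin, 0.276 for DNA replication, and 0.485 each for leaf and meristem regulators, photosynthesis and stress. On the second it was 0.225 for chromatin, 0.225 for leaf and meristem regulators and 0.465 for photosynthesis. The correlation estimated for the leaf and meristem list of the second set was −0.016, below the preset 0.01. Its unadjusted camera p still rose, from 0.00147 to 0.0281. These lost calls therefore cannot be read as an effect of correlation between genes alone. The stress list of the first set had adjusted p = 0.0831 in the medium scan, 0.0786 in the high scan, 0.0576 without the dye term, 0.0509 with SAM in Cy3 alone, 0.0665 with SAM in Cy5 alone, and 0.0251 to 0.062 without single replicates (0.062 without replicate 5); the cause was not tested. With SAM in Cy5 alone 3 lists passed on the first set, the leaf and meristem list at 0.0516, on fewer slides. The replication list of the second set passed without members matched by name only (0.0184; 0.465 with an estimated correlation) and with SAM in Cy3 alone (0.0259). The dye count was 11 (low scan) and 1540 (medium scan) on the first set and 414 (low scan) on the second; the cause was not tested. The ratio of ocl2 on the first set reversed to −0.0523 with SAM in Cy5 alone; the cause was not tested. Other reversals were below the threshold before and after: wox13B on the first set was 0.2919 with SAM in Cy3 alone and −0.2111 to 0.0643 without single replicates, positive without replicate 3, and ns2 on the second set was −0.0666 in the medium scan. By the side of the camera test, 3 lists that did not pass also turned, with adjusted p as follows. The hormone list turned without members matched by name only (0.988 and 0.687 in the sets), with SAM in Cy5 alone (0.99 and 0.837) and, on the first set, without replicate 1 (0.838 to 0.939 without single replicates). The cytoskeleton list of the first set turned with slides scaled to the same spread (0.976), with SAM in Cy5 alone (0.714) and without replicate 2, 3, 4 or 5 (0.849 to 0.998). Translation factors turned with SAM in Cy3 alone (0.764 and 0.729) and without replicate 6 (0.849 to 0.947 on the first set and 0.794 to 0.964 on the second without single replicates). The cause was not tested. Of the other values of named genes, 2179 kept their direction and side of the threshold and 44 lost the call. Asking for a value in every replicate or scan removed no probe and says nothing. By fry, against 0, other lists that did not pass camera had these adjusted p. On the first set histones had 0.000475, knotted1-like genes 0.0211 and nitrogen assimilation 1.45e-05. On the second, knotted1-like genes had 0.000439, nitrogen assimilation 8.97e-05 and chlorophyll 8.97e-05. There stress had 7.97e-05, vascular tissue 7.97e-05 and replication 0.136. Signal over background is not known from ratios. In each low scan of the first set, 4.174% to 8.163% of probes held the shared value read as both channels at the floor. At most 0.891% did in its high scans. Probes with a single channel at the floor are not counted there.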

Other observations

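All tests of this part were written before the results they measure were seen.

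Large ratios were more often on the seedling side. At least 32-fold, 448 probes lay on the seedling side and 76 on the SAM side of the first set, and 209 and 37 on the second, ratios of 5.89 and 5.65. A floor in the weaker scans is argued against as the whole cause, since the high scan alone gave 6.08 and 4.97, and so is the dye, since the lower of the orientations gave 5.03 and 3.32. Photosynthesis and chlorophyll genes made up 7 of 37 named genes in this tail on the first set (Fisher's exact test, two-sided, p = 1.05e-05) and 6 of 19 on the second (p = 9.07e-06), but the seedling side was named from the photosynthesis list, so these values restate its position and decide nothing. A floor in a single channel can lie in the high scan too and cannot be read from a ratio, so it stays open. A difference between the tissues, and the difference in their extraction, also stay open.

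For the 10 genes on opposite sides, spots with both channels at the floor are argued against as the whole cause, since 1 of the 10 had such a probe, against 20 of 166 genes on the same side (Fisher's exact test, two-sided, p = 1). A floor in a single channel cannot be read from a ratio and stays open. A difference between the slide sets in hybridisation or scaling also stays open: probes of a gene differed between sets by 0.99 times as much as within the first set over 181 genes, but that test needs 2 probes on the first set and left out 5 of the 10, the 4 largest contrasts among them. Which transcript each clone detects was not tested and stays open.

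Of 32 ways of turning the signs of the 6 slides, only the real one gave as many probes (1 in each set). The first set had 11437 against a highest other of 0, and the second 7769 against 252. So it was for the gene counts (1 in each set), 421 against a highest other of 1, and 335 against 2. These counts argue against chance but cannot exclude it, since 1 in 32 is the smallest share possible. Turning a slide also moves shared ratios into the residual, so low counts elsewhere follow once the slides agree. A difference common to all slides, such as the extraction, is not addressed. For the list counts chance could not be excluded: 4 ways gave as many as the real 5 on the first set, with a highest other of 5, and 16 gave as many as the real 3 on the second, with a highest other of 5. Ways that turned 1 or 2 slides keep part of the real contrast, and those that turned 3, which keep none, gave at most 3 and 1 lists.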
